A study of Aspergillus nidulans with 24 samples.

How the data were processed

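RNA came from frozen mycelium of A. nidulans, was extracted with a Zymo Quick-RNA kit, and had an integrity number of at least 8, per the labels' protocols. Libraries were made with the Illumina TruSeq Stranded mRNA kit and sequenced. The 24 libraries fell into 8 groups of 3, 1 for each of 4 strains at 2 h and at 8 h in 2% maltose medium at 37 °C. The labels call the 3 libraries of a group biological triplicates. Supplements of pyridoxine and of uracil and uridine were given as needed, and which strain received which is not stated in them.

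The authors deposited 1 table of FPKM values (fragments scaled for gene length and for the total of the library), with 1 column per library and 1 line for each of 10631 genes. The submitters' processing notes name bcl2fastq 1.8.4, FastQC, SAMtools 0.1.18, HTSeq 0.6.0 and DESeq2, with no role or order. The aligner, the genome build, the annotation and the gene lengths used are not given in the sources used here. Whether the authors' counting used the strand is not given either, so reads of a gene and of an overlapping or antisense neighbour may not be separated, and near-identical genes may share reads. The FPKM values were not scaled between libraries as far as they show.

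The values of each gene were whole multiples of a step that depended on the gene and the library. From these steps whole reads were recovered for 10631 of 10631 genes (100.0%, within a tolerance of 0.02, largest deviation 0.00068). The totals ran from 7140121 (AbfA at 8 h, replicate 2) to 32309717 (AbfA at 2 h, replicate 1). The 10 most abundant genes held 4.46% to 9.82% of the reads of a library. Of 7825 genes with enough reads to give a length, 7808 had a length that was a multiple of 3, so the lengths are coding lengths. Because FPKM divides by the total of the library, an abundant introduced gene lowers the values of all other genes slightly, which median-of-ratios scaling between libraries was used to check. That scaling centres the median change of a comparison near 0, so it nearly fixes a roughly even split of higher and lower genes. The shares of higher genes after scaling are therefore no separate finding.

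Gene names came from a table of the RefSeq assembly ASM1142v1, which was used for names and for which genes neighbour each other, with no coordinates. It held 9938 of the IDs and gave 778 of them a symbol. Other names are those of gene lists that were written from textbook knowledge before the data were examined, and were not checked against an annotation. Of 128 IDs in those lists, 64 had a symbol in the table, of which 17 had another symbol, 63 had none, and 1 was not among the genes measured. Where ID and symbol clashed, the gene that bears the listed symbol in the table was used, if there was one. By this AN4566 and AN7032 are in the fixed list of cell wall synthesis under their symbols in the table, chsA and chsB.

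Expression was compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for the 9201 genes with an FPKM of at least 1 in at least 3 libraries. A single fit held the 8 group means over all 24 libraries, with empirical Bayes moderation that followed the trend of the variance with the mean. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, and every adjusted p of a single gene in the text is from this two-sided limma test, or from limma's F-test among the 3 strains, unless another setting is named. The comparisons were each recombinant strain against the parental strain at each time, the 3 recombinant strains among each other at each time, 8 h against 2 h in each strain, and the change of each strain's difference from the parental strain between the times. Groups of genes called the same way in all 3 strains were counted, with the overlap of independent lists and of simulated unchanged groups against the same parental libraries beside them. The libraries of every called gene were also compared for overlap: in the 10 comparisons of 3 with 3 libraries, 34% to 57.4% of all genes did not overlap, where chance gives 10%.

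Gene lists were tested with camera of limma, with a preset correlation of 0.01 between genes, and again with an estimated correlation. At least 3 members had to be measured, which left 31 lists, and 403 tests over 13 comparisons. Lists fixed beforehand have a count adjusted over the list alone beside the count over all genes. A further 16 of the lists in use, among them ribosome biogenesis, proteasome, sterol synthesis, zinc uptake, ribosomal proteins and those by symbol, were drawn up from the names table after the table was seen and before any group was tested. Their members were entered by symbol and not checked by function, and the place of nopA in ribosome biogenesis is doubtful. The lists of heat shock genes, of siderophores and of cell wall genes overlap. Of 84 calls (50 up, 34 down), 1 held with an estimated correlation.

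The genes named in the text follow a rule written before the data were examined. They are 10 genes of the secretory pathway, pyrimidine synthesis and maltose use; in each comparison the 8 largest increases and decreases among called, named genes whose 3 libraries do not overlap those of the other group, with the 2 largest of any naming; the 8 largest in each direction shared by the 3 strains; the 4 largest of each sign in each test of a changed difference; and up to 2 called members of each list per direction. The text gives them in order of size and not all of them. The introduced genes are given as levels, since their fold against strains at about 0 depends on the pseudocount.

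Replicate numbers did not pair the libraries in general. In the 8 h against 2 h comparison of BglC, however, the deviations from the group means correlated between libraries of the same number (0.59, 0.15 and 0.33), a hint from the data, since the labels do not say what a number stands for. With the replicate number as a block, that comparison gave 2865 genes over all 24 libraries, against 2974 without it. Fitted to the 6 libraries of BglC alone it gave 2471, against 1778 without the block. No pair of replicates looked like 1 library read in 2 times: the lowest chi-square per gene between the recovered reads of replicates was 19.5. At 2 h AbfA replicate 1 stood apart from the other replicates of its group (127.3 and 229, against 28.29 between those). So did BglC replicate 1 (137.2 and 83.23, against 48.63). Without these libraries the counts against the parental strain at 2 h rose to 3520 in AbfA and 3064 in BglC.

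The alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, no trend in the moderation, the replicate block, only the libraries of the groups compared in the fit, camera with an estimated correlation, and leaving out each library in turn. limma voom on the recovered reads, thinning of those reads to the depth of the shallowest library, and the block within BglC alone were added afterwards. The main test was tested on simulated data with 8838 genes. For AbfA against the parental strain at 2 h it found 81% of genes changed 2-fold and 32% of those changed 1.5-fold, and called 6 unchanged genes. For the changed difference in AbfA it found 47% and 6%. The simulated noise was drawn for each gene and library separately, with 1 spread per gene over all groups. A library that stands apart as a whole, as AbfA replicate 1 at 2 h does, was thus not simulated. The 6 calls are therefore no estimate of false calls in the real comparison. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were prepared with numpy 2.4.6 and pandas 2.3.3.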

Results

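RNA was sequenced from mycelium of 4 strains of the filamentous fungus Aspergillus nidulans. Each of 3 recombinant strains made 1 heterologous enzyme: AbfA made an alpha-arabinofuranosidase, BglC a beta-glucosidase, and 1542 a thermophilic mannanase. The other strain was their parent, A773, which carries mutations in pyrG, wA and pyroA. Mycelium grown on glucose was moved to minimal medium with 2% maltose, the sugar that switches on the promoter of the introduced genes, and sampled after 2 h and 8 h. Each of the 8 combinations of strain and time had 3 libraries from biological replicates, 24 libraries in all. Expression was given as FPKM for 10631 genes, of which 3 were the introduced genes. The whole reads recovered from the FPKM values came to between 7140121 and 32309717 per library, so that 1 read in a gene of 1 kb stood for 0.031 to 0.1401 FPKM. A level is given as mean FPKM ± SD and a change as log2 ± SE from limma, with n = 3 libraries in every group. The SE rests on 1 spread per gene, taken over all 24 libraries, and not on the spread of the 2 groups compared. It can understate the spread where libraries of a group differ more, as in AbfA at 2 h (pyrG from 455.2 to 1169 FPKM). A change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. Where a name stands in brackets after an AN identifier, it is the name under which the gene was entered in the lists fixed beforehand.

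The libraries separated by time and by strain. The first principal component held 27.9% of the variance and parted the 2 h from the 8 h libraries within each strain. The second held 24% and parted AbfA and 1542, at low values, from BglC and the parental strain, at high values.

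**Figure D1:**
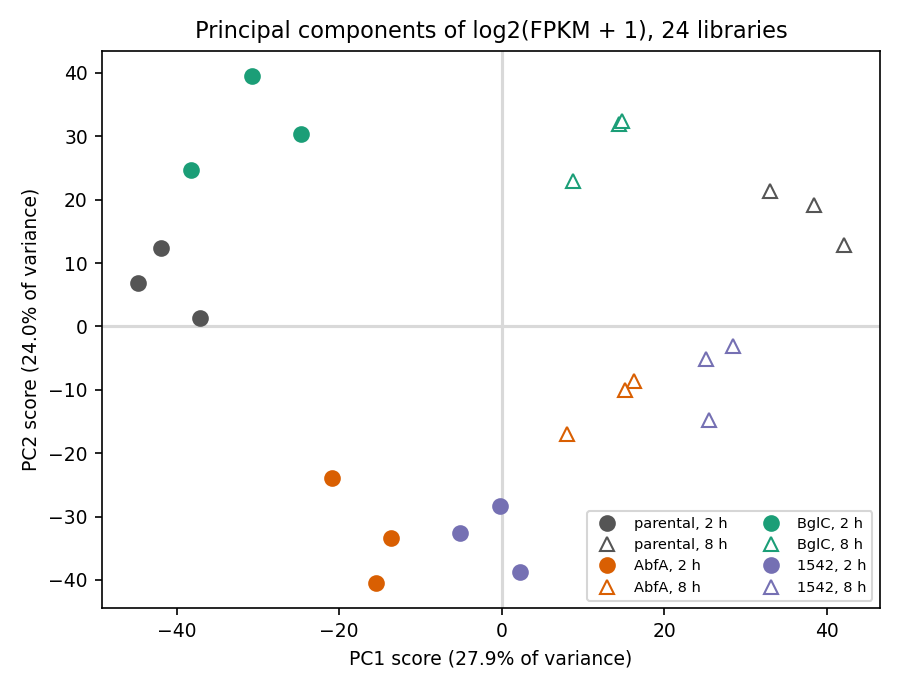
Position of each of the 24 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis (27.9% and 24%). Colours stand for strains and symbols for time, and within each strain the 2 h and 8 h libraries lie apart on the first component.

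Each introduced gene was abundant in its own strain at both times and close to 0 in the other strains. The BglC gene reached 7236 ± 1263 FPKM at 2 h and 8617 ± 676 at 8 h in BglC, which placed it between rank 6 and rank 15 of all genes. The AbfA gene reached 4194 ± 1847 and 4867 ± 1092 FPKM in AbfA, and the mannanase gene 913 ± 189 and 938 ± 132 FPKM in 1542. In the libraries of the other strains these genes had 0 to 77 reads, and at most 1.98 FPKM. The pyrG gene encodes orotidine 5'-phosphate decarboxylase of pyrimidine synthesis and is mutated in the parental strain. Its RNA was higher in all 3 recombinant strains at both times. The parental strain held 64.1 ± 2.59 FPKM at 2 h and 69.2 ± 7.04 at 8 h. AbfA held 704 ± 403 and 678 ± 133 FPKM, BglC 204 ± 19.3 and 237 ± 14.2, and 1542 176 ± 15.8 and 158 ± 3.49. The log2 changes from the parental strain were 3.30 and 3.26 in AbfA, 1.65 and 1.77 in BglC, and 1.44 and 1.19 in 1542 (SE 0.23), and each passed the limma test in every setting tried. Levels differed among the 3 strains at 2 h (limma adjusted p = 4.7e-06) and at 8 h (adjusted p = 1.5e-05). AN0565 (pyrABCN), which encodes the enzyme of the first steps of pyrimidine synthesis, went the other way where it passed. It was lower in AbfA at 8 h (−0.67 ± 0.18), in BglC at 8 h (−0.92 ± 0.18) and in 1542 at both times (−0.67 ± 0.18 and −0.89 ± 0.18). The call in AbfA at 8 h ended without parental replicate 3 (adjusted p = 0.064).

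**Figure D2:**
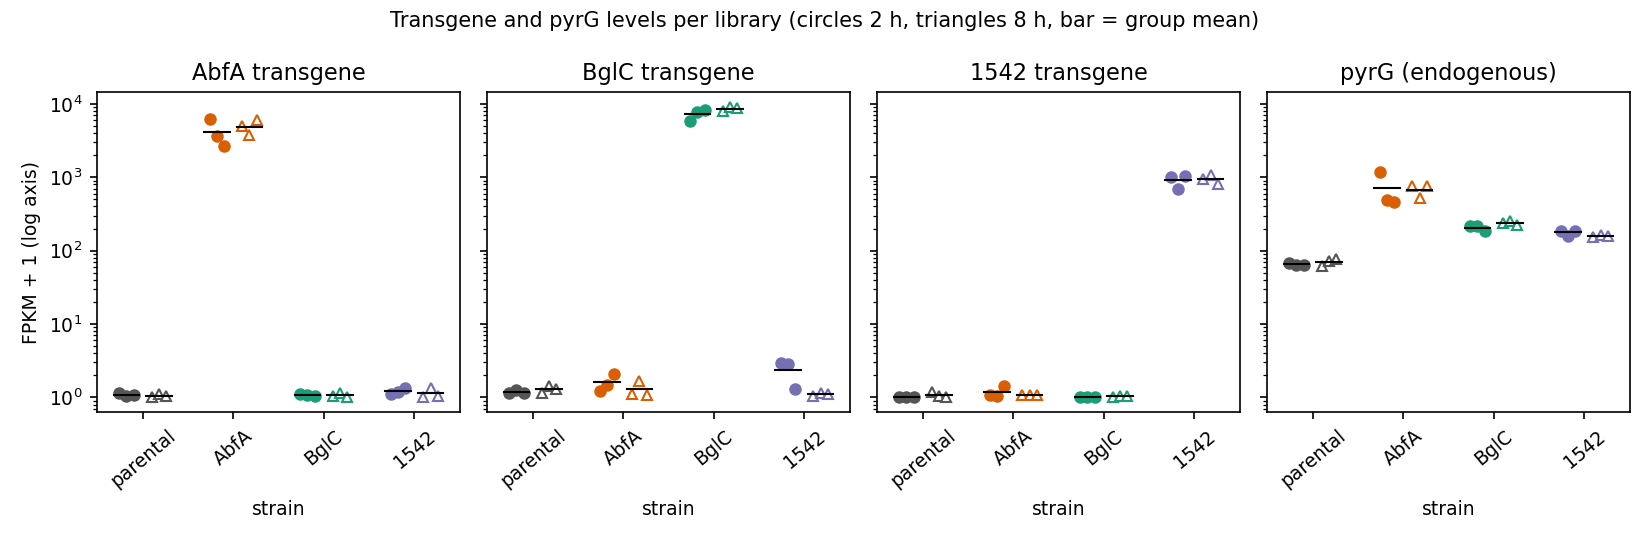
FPKM + 1 of the 3 introduced genes and of pyrG on a log axis, by strain, with filled circles for libraries at 2 h, open triangles for libraries at 8 h and bars for the means of 3. Each introduced gene stood at a mean of at least 913 FPKM in its own strain and at most 1.98 FPKM in any library of the others, and pyrG was lowest in the parental strain.

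In AbfA at 2 h lists of siderophore, ethanol and heat shock genes passed upward against the parental strain, and lists for starch use, the cell wall, sterols and ribosome assembly downward, with at least 0.5 of the members of each called in that direction. None of these calls held with an estimated correlation between genes (adjusted p = 0.45 to 0.53). Besides pyrG, the largest increases among the genes named by rule were in mirB, a siderophore transporter (3.17 ± 0.67), arp1 (2.94 ± 1.04), AN0399 (nrtB), a nitrate transporter (2.88 ± 0.51), and AN8979 (alcA), an alcohol dehydrogenase (2.67 ± 0.44). Next came fahA and maiA, which encode enzymes of phenylalanine and tyrosine breakdown (2.65 ± 0.42 and 2.62 ± 0.35). The largest decreases were in mep20, a metalloprotease gene, from 267 ± 111 to 17.1 ± 9.95 FPKM (−3.98 ± 0.55), in AN2622 (ipnA) of penicillin synthesis (−2.40 ± 0.69), in AN5558 (prtA), a protease (−2.20 ± 0.45), in AN3402 (amyB), an amylase (−2.13 ± 0.46), and in medA, a regulator of development (−2.03 ± 0.33). Of genes of any naming, AN6693 rose most after the introduced gene (4.12 ± 0.56) and AN8737 fell by 3.59 ± 0.52. In all, 2939 of 9201 genes differed (1700 higher, 1239 lower), of which 821 changed at least 2-fold. After scaling between libraries 51.1% of the changed genes were higher, against 57.8% before. The calls of arp1 and AN2622 rested on single libraries. That of arp1 ended without parental replicate 2 (adjusted p = 0.12) or 3 (0.11), without AbfA replicate 2 (0.14) or 3 (0.14), and with voom on recovered reads (0.25). That of AN2622 ended without parental replicate 3 (0.073) or AbfA replicate 3 (0.055). With only the 6 libraries compared in the fit, the calls of arp1 (0.056) and AN3402 (0.064) ended, and the count of genes was 1319. The count was 1747 without parental replicate 2, 1908 without parental replicate 3, and 1947 without AbfA replicate 2.

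Gene lists gave the same comparison by function. All 5 heat shock genes of the list fixed beforehand were higher in AbfA at 2 h, 5 also when adjusted over the list alone (camera adjusted p = 0.0031, and adjusted p = 0.53 with an estimated correlation). AN5781 (hsp30) rose from 3760 ± 1360 to 14700 ± 2810 FPKM (2.01 ± 0.34), and AN0858 (hsp104), a disaggregase, by 1.43 ± 0.31. An overlapping list of 9 heat shock genes by symbol had 8 higher and 0 lower (adjusted p = 0.0029, and 0.53 as adjusted p with an estimated correlation). Of 12 siderophore genes, 6 were higher and 0 lower, with sidJ at 1.56 ± 0.30 (adjusted p = 0.016, and adjusted p = 0.53 with an estimated correlation). Of 6 genes of ethanol use, 4 were higher, 4 also when adjusted over the list alone (adjusted p = 0.046, and adjusted p = 0.53 with an estimated correlation), among them AN3741 (alcB) at 2.01 ± 0.36. That list's call ended without parental replicate 3 (0.087) or AbfA replicate 1 (0.19). In the other direction, 16 of 29 ribosome biogenesis genes were lower and 0 higher, such as mrd1 (−0.73 ± 0.16) and dbp9 (−0.70 ± 0.13) (adjusted p = 1.2e-05, and adjusted p = 0.53 with an estimated correlation). Of 9 genes of starch and maltose use, 6 were lower, 6 also when adjusted over the list alone (adjusted p = 0.0029, and adjusted p = 0.45 with an estimated correlation). Of 22 cell wall enzymes, 11 were lower and 3 higher, with the chitin synthase genes chsA (−1.45 ± 0.25) and chsG (−1.04 ± 0.15) among the lower (adjusted p = 0.0019, and adjusted p = 0.53 with an estimated correlation). Of 17 sterol synthesis genes, 9 were lower, such as erg2 (−1 ± 0.22) and erg24B (−0.77 ± 0.17), and 1 was higher, idi1 (0.53 ± 0.15) (adjusted p = 0.0031, and adjusted p = 0.53 with an estimated correlation). The lists of ribosomal proteins (3 of 13 lower, adjusted p = 0.016), glycosylation (2 of 9 lower, 0.034) and glycolysis (3 of 9 lower and 1 higher, 5 and 1 adjusted over the list alone, 0.046) also passed, with adjusted p = 0.54, 0.53 and 0.53 with an estimated correlation. Without parental replicate 3 the calls of ribosomal proteins (0.058) and glycosylation (0.058) ended, and glycosylation also without AbfA replicate 1 (0.072). Glycolysis ended without parental replicate 1 (0.068) or AbfA replicates 2 (0.059) or 3 (0.081), and after scaling between libraries (0.066).

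At 8 h the lists of conidiation and of acetate and ethanol use passed upward in AbfA, and that of the proteasome downward, each through a part of its members. With an estimated correlation between genes none of these calls held (adjusted p = 0.75 to 0.90). ivoB, needed for the brown pigment of conidiophores, was at 307 ± 85.5 FPKM against 3.84 ± 1.49 (5.99 ± 0.42). The hydrophobin gene rodA followed (3.74 ± 1.15), then ags2, an alpha-glucan synthase (3.45 ± 0.21), ivoA (2.68 ± 0.39), mep20 (2.57 ± 0.55), AN8979 (alcA, 2.24 ± 0.44) and AN0554 (aldA), an aldehyde dehydrogenase (2.22 ± 0.28). gmdB was lower (−2.24 ± 0.23), as were tpcA (−1.76 ± 0.44), aspf13 (−1.57 ± 0.39), aspf34 (−1.56 ± 0.21) and aah1 (−1.48 ± 0.23). Of genes of any naming, AN2573 (−4.40 ± 0.28) and AN5459 (−2.99 ± 0.23) fell most. Of 9201 genes, 2570 differed (1039 higher, 1531 lower), and after scaling 48.8% of the changed genes were higher, against 40.4% before. At least 2-fold changes were found in 626, and among them the majority was the other way (421 higher, 205 lower). By list, 4 of 7 genes of acetate use and gluconeogenesis were higher, 5 when adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.75 with an estimated correlation), with AN6653 at 1.86 ± 0.25. Of 11 conidiation genes, markers of conidiophores that a culture of mycelium could hold, 4 were higher, 5 when adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.75 with an estimated correlation), with the regulator brlA at 1.96 ± 0.44. Of 15 proteasome genes, 6 were lower, such as pre2 (−0.51 ± 0.11) and pre8 (−0.50 ± 0.11) (adjusted p = 0.013, and adjusted p = 0.90 with an estimated correlation). Ethanol use (4 of 6 higher, 4 adjusted over the list alone, adjusted p = 0.03), the 5 heat shock genes (4 higher, 4 adjusted over the list alone, 0.015) and the 9 heat shock genes (4 higher, 0.03) passed too, with adjusted p = 0.75, 0.90 and 0.90 with an estimated correlation. All 3 calls ended without parental replicate 1 (0.061, 0.061 and 0.14), and those of ethanol use (0.053) and the 9 heat shock genes (0.076) after scaling between libraries. The call of rodA ended without any one of the parental replicates 1 to 3 (0.053, 0.05 and 0.057) or AbfA replicates 2 and 3 (0.065 and 0.068). The count fell to 1363 without parental replicate 3, 1655 without parental replicate 1, 1689 without AbfA replicate 2 and 1648 without AbfA replicate 3.

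In BglC at 2 h lists of heat shock genes passed upward, and lists of glycolysis, amino acid synthesis and ribosomal proteins downward. Each lost its call with an estimated correlation between genes (adjusted p = 0.35 to 0.60). Its largest increases among the genes named by rule were in tmpA, a membrane oxidoreductase of conidiation (2.27 ± 0.62), gatA, a GABA transaminase (1.91 ± 0.43), aspf34 (1.74 ± 0.21), pyrG, pmcC, a calcium pump (1.64 ± 0.30), and hsp78, a mitochondrial chaperone (1.63 ± 0.41). The largest decreases were in ivoB (−3.11 ± 0.42), ags2 (−1.66 ± 0.21), fbp1, a fructose-1,6-bisphosphatase (−1.36 ± 0.11), luA of leucine synthesis (−1.34 ± 0.17) and agdC (−1.22 ± 0.20). AN0284, of any naming, was at 61.7 ± 9.3 FPKM against 0.754 ± 0.0831 (5.15 ± 0.13), and AN8890 fell by 2.87 ± 0.65. All 9 heat shock genes by symbol were higher (camera adjusted p = 4.7e-07, and adjusted p = 0.35 with an estimated correlation). So were the 5 of the list fixed beforehand, 5 also when adjusted over the list alone (adjusted p = 2.5e-05, and adjusted p = 0.35 with an estimated correlation), with AN5781 (hsp30) at 1.45 ± 0.34 and hsp60 at 1.37 ± 0.21. Of 9 glycolysis genes, 6 were lower, 8 when adjusted over the list alone (adjusted p = 0.0025, and adjusted p = 0.35 with an estimated correlation), such as AN2875 (fbaA, −1.09 ± 0.16) and pgkA (−0.93 ± 0.20). Of 22 genes of amino acid synthesis, 11 were lower, with luA and ilv3B (−1.09 ± 0.22) in front (adjusted p = 0.00062, and adjusted p = 0.60 with an estimated correlation). Of 13 genes of ribosomal proteins and translation initiation, 8 were lower (adjusted p = 0.0015, and adjusted p = 0.60 with an estimated correlation). Of 15 genes of the sterigmatocystin cluster, 3 were higher and 1 lower, 9 and 1 when adjusted over the list alone (adjusted p = 0.0046, and adjusted p = 0.60 with an estimated correlation). Of 22 cell wall enzymes, 6 were higher, such as bgt2 (0.96 ± 0.18), and ags2 was lower (adjusted p = 0.004, and adjusted p = 0.54 with an estimated correlation). Acetate use (4 of 7 lower, 4 adjusted over the list alone, adjusted p = 0.034) and cell wall synthesis (1 of 4 higher, 2 adjusted over the list alone, 0.034) passed with adjusted p = 0.60 for both with an estimated correlation. Without parental replicate 1 the calls of cell wall enzymes (0.057), acetate use (0.057) and cell wall synthesis (0.17) ended, and the last pair also without BglC replicate 1 (0.088 and 0.13).

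In this comparison 2135 of 9201 genes differed (690 higher, 1445 lower). Of these 408 changed at least 2-fold, and among them the majority was the other way (265 higher, 143 lower). The median over all genes was −0.104. After median-of-ratios scaling between libraries the share of higher among changed genes was 48.7%, against 32.3% before. The count was 637 with only the 6 libraries compared in the fit, 976 without BglC replicate 3, 1246 without BglC replicate 2, 1173 without parental replicate 2 and 1299 without parental replicate 3. The call of tmpA ended without BglC replicate 2 (adjusted p = 0.066) and with voom on recovered reads (0.079), and that of AN8890 with only those 6 libraries (0.051).

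At 8 h the lists of heat shock genes and, through 3 of 9 members, of starch and maltose use passed upward in BglC, and the proteasome downward. These calls too were lost with an estimated correlation between genes (adjusted p = 0.24 to 0.64). mep20 rose by 4.08 ± 0.55, arp1 by 3.96 ± 1.04, AN5558 (prtA) by 2.56 ± 0.45, tpcI by 2.52 ± 0.70, tmpA by 2.48 ± 0.62 and nrps1 by 2.21 ± 0.34. AN7402 (glaB), a glucoamylase, followed (2.02 ± 0.26), then ivoB (1.93 ± 0.42). Among the genes named by rule the decreases were led by gmdB (−3.29 ± 0.23), tpcA (−2.09 ± 0.44), AN6932 (uapA), a purine transporter (−1.81 ± 0.59), AN0399 (nrtB, −1.62 ± 0.51) and aah1 (−1.52 ± 0.23). AN0284 was at 121 ± 11.5 FPKM against 0.639 ± 0.0491 in the parental strain, while AN2573 (−4.92 ± 0.28) and AN7894 (−4.64 ± 0.94) fell most of all genes. All 15 proteasome genes were lower, such as pre3 (−0.79 ± 0.16) and pre4 (−0.63 ± 0.14) (adjusted p = 0.00013, and adjusted p = 0.64 with an estimated correlation). All 5 heat shock genes of the fixed list were higher, 5 also when adjusted over the list alone (adjusted p = 0.00057, and adjusted p = 0.54 with an estimated correlation), and 6 of the 9 by symbol (adjusted p = 0.00013, and adjusted p = 0.54 with an estimated correlation). Of 9 genes of starch and maltose use, 3 were higher, 3 also when adjusted over the list alone (adjusted p = 6e-04, and adjusted p = 0.24 with an estimated correlation), among them AN7402 and AN11143 (1.22 ± 0.20). The sterigmatocystin cluster passed upward (adjusted p = 0.047, and adjusted p = 0.82 with an estimated correlation), although 1 member was higher and 2 lower over all genes and 0 adjusted over the list alone. Its call ended in 6 settings, among them scaling between libraries (0.27) and the fits without parental replicate 1 (0.11) or BglC replicate 1 (0.63).

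Here 2576 genes differed (652 higher, 1924 lower), 607 at least 2-fold (293 higher, 314 lower), around a median over all genes of −0.145. After scaling between libraries 49.6% of the changed genes were higher, against 25.3% before. The count was 1558 without BglC replicate 3 and 1658 without parental replicate 3. Without BglC replicate 3 the calls of arp1 (adjusted p = 0.063), tpcI (0.087) and AN0399 (0.063) ended. AN0399 was also lost without parental replicates 1 (0.055) or 3 (0.081) or BglC replicate 2 (0.059), and AN6932 without parental replicates 1 to 3 (0.054, 0.072 and 0.071) or BglC replicate 1 (0.12).

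The mannanase strain 1542 differed from its parent in the most genes of the 3 strains at 2 h with all libraries in the fit, although without AbfA replicate 1 the count in AbfA was as high (3520). Among the genes named by rule the largest increases were in iron, nitrate and ethanol genes. mirB was at 160 ± 103 FPKM against 3.42 ± 1.01 (4.94 ± 0.67), the nitrate transporter gene AN0399 (nrtB) at 151 ± 25.7 against 7.40 ± 6.01 (4.41 ± 0.51), and AN8979 (alcA) at 1160 ± 139 against 58.6 ± 24 (4.38 ± 0.44). They were followed by crnA, a nitrate transporter (4.16 ± 0.89), sidI of siderophore synthesis (3.15 ± 0.64), tmpA (3.09 ± 0.62) and niaD, the nitrate reductase gene (3.04 ± 0.56). The decreases among the named genes were led by mep20 (−4.35 ± 0.55), AN5558 (prtA, −1.99 ± 0.45), medA (−1.99 ± 0.33), AN3402 (amyB, −1.79 ± 0.46), aspf13 (−1.65 ± 0.39) and chsA (−1.59 ± 0.25). Of genes of any naming, AN8308 rose from 5.33 ± 1.66 to 1110 ± 525 FPKM (7.35 ± 0.76) and AN6103 fell by 4.17 ± 0.57. Of 9201 genes, 3517 differed (2033 higher, 1484 lower), 935 at least 2-fold, and no single library moved this count by more than 1.5 times. The majority of higher genes depended on the scaling, which centres the median change near 0. After it 49.3% of the changed genes were higher, against 57.8% before.

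Of 29 ribosome biogenesis genes, 23 were lower in 1542 at 2 h and 0 higher, such as pxr1 (−1.01 ± 0.16) and drs1 (−0.99 ± 0.16) (camera adjusted p = 3.8e-10, and adjusted p = 0.42 with an estimated correlation). Of 12 siderophore genes by symbol, 10 were higher (adjusted p = 0.00018, and adjusted p = 0.42 with an estimated correlation), and of 7 iron uptake genes of the fixed list 5, also 5 when adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.42 with an estimated correlation). Of 6 genes of ethanol use, 4 were higher, 4 also when adjusted over the list alone (adjusted p = 0.0034, and adjusted p = 0.40 with an estimated correlation), with AN0554 (aldA) at 2.30 ± 0.28. Of 4 zinc uptake genes, 3 were higher, such as zrfC (1.87 ± 0.20) and zrfA (1.33 ± 0.29) (adjusted p = 0.024, and adjusted p = 0.40 with an estimated correlation). Heat shock genes were higher again, 5 of the 5 in the fixed list and 5 adjusted over the list alone (adjusted p = 0.019), and 8 of the 9 by symbol with 1 lower (adjusted p = 0.016). Both had adjusted p = 0.45 with an estimated correlation. Of 15 proteasome genes, 6 were higher (adjusted p = 0.014, and adjusted p = 0.48 with an estimated correlation). Sterol synthesis (10 of 17 lower and 2 higher), cell wall enzymes (11 of 22 lower and 1 higher) and ribosomal proteins (6 of 13 lower) each had adjusted p = 0.014, and adjusted p = 0.45, 0.42 and 0.45 with an estimated correlation. The sterol genes erg2 (−0.92 ± 0.22) and hmg1 (−0.85 ± 0.11) were among the lower.

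Of 10 genes of protein folding in the endoplasmic reticulum, 5 were lower in 1542 at 2 h and 2 higher, 6 and 2 when adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.42 with an estimated correlation). Of 8 genes of transport from the endoplasmic reticulum to the Golgi, 4 were lower, such as bfr1 (−0.55 ± 0.12) and sec13 (−0.46 ± 0.11) (adjusted p = 0.041, and adjusted p = 0.45 with an estimated correlation). Amino acid synthesis had 6 of 22 genes lower (adjusted p = 0.037, and adjusted p = 0.48 with an estimated correlation). Nitrogen uptake had 7 of 13 higher and 2 lower, 7 and 2 adjusted over the list alone (adjusted p = 0.044, and adjusted p = 0.45 with an estimated correlation). All 4 calls ended without 1542 replicate 2 (0.072, 0.064, 0.064 and 0.072). Transport ended also without parental replicate 2 (0.064), amino acid synthesis without parental replicate 3 (0.12), and nitrogen uptake without 1542 replicate 1 (0.068), without parental replicate 1 (0.072) and with voom (0.051).

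At 8 h the lists of ethanol, acetate and starch use passed upward in 1542 and that of the proteasome downward, each with no more than 0.5 of its members called. No call among them held with an estimated correlation between genes (adjusted p = 0.22 to 0.92). ivoB was at 245 ± 93.7 FPKM against 3.84 ± 1.49 (5.65 ± 0.42), ags2 at 22.4 ± 6.29 against 1.68 ± 0.101 (3.10 ± 0.21), and aspf2 at 65.3 ± 3.42 against 9.02 ± 1.71 (2.74 ± 0.23). sclB, a regulator of development, followed (2.28 ± 0.19), then AN8979 (alcA, 2.07 ± 0.44), tmpA (1.97 ± 0.62) and AN0554 (aldA, 1.76 ± 0.28). aspf13 fell from 764 ± 178 to 81.7 ± 26.6 FPKM (−3.24 ± 0.39), gmdB from 71.2 ± 14.2 to 9.55 ± 0.37 (−2.76 ± 0.23), tpcA by 2.18 ± 0.44, and aah1 by 1.95 ± 0.23. The xylanase genes AN1818 (xlnC, −1.35 ± 0.28) and AN9365 (xlnB, −1.19 ± 0.25) were lower too. Of any naming, AN2573 (−4.89 ± 0.28) and AN7378 (−4.26 ± 0.26) fell most. Of 6 genes of ethanol use, 3 were higher, 4 when adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.22 with an estimated correlation). Starch and maltose use had 3 of 9 higher, 3 adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.22 with an estimated correlation), and acetate use 3 of 7, 4 adjusted over the list alone, with acuF and AN6653 both at 1.19 (adjusted p = 0.0019, and adjusted p = 0.42 with an estimated correlation). Of 15 proteasome genes, 5 were lower, such as pre8 (−0.44 ± 0.11) (adjusted p = 0.0041, and adjusted p = 0.92 with an estimated correlation). The 5 heat shock genes passed with 1 higher over all genes and 4 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.86 with an estimated correlation). The 9 by symbol did not pass (0 of 9 called, adjusted p = 0.11). The call of the 5 ended after scaling between libraries (0.064) and without 1542 replicate 3 (0.21) or parental replicate 1 (0.08). Of 9201 genes, 1670 differed (499 higher, 1171 lower), 476 at least 2-fold (198 higher, 278 lower). After scaling, 48.4% of the changed genes were higher, against 29.9% before. The count was 957 without 1542 replicate 3, 1083 without 1542 replicate 1, 987 without parental replicate 1 and 988 without parental replicate 3. The call of tmpA ended without 1542 replicates 1 to 3 (0.069, 0.1 and 0.059), without parental replicates 1 (0.1) or 3 (0.12), and with voom (0.052).

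**Figure D3:**
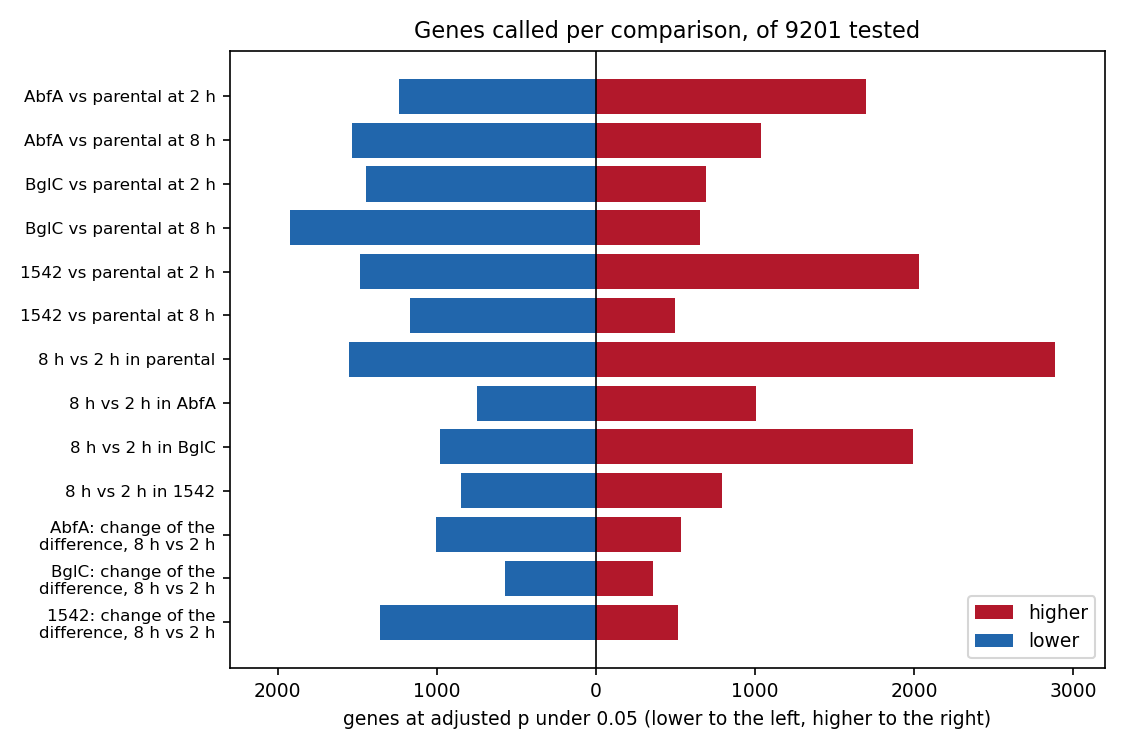
Number of genes that passed the limma test in each comparison that has a direction, out of 9201 tested, with genes lower to the left and higher to the right. Of these, the change between the times in the parental strain has the most, with 1550 lower and 2890 higher, and the change of the BglC difference with time the fewest, with 572 and 361.

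Some genes changed the same way in all 3 strains against the parental strain. At 2 h they were 353 (187 higher, 166 lower), where independent lists of the same sizes would share 28.2 and 31.4. At 8 h they were 701 (116 higher, 585 lower), where independent lists would share 4 and 40.7. Simulated unchanged groups against the same parental libraries shared 0 in 50 simulations. That value is nearly fixed, because with no gene changed the adjusted cut-off is far stricter than in the real lists. It is therefore no baseline for 353 and 701. The parental group of 3 could not be split, so part of the excess may come from the shared parental libraries. The parental strain also carries the pyrG mutation and had less pyrG RNA, and the supplements given to each strain are not stated. Shared changes can therefore not be assigned to production of the enzymes. Shared increases at 2 h were pyrG, AN5781 (hsp30), hsp78 and AN0858 (hsp104), next to tmpA, AN0399 (nrtB), gatA and sxa2. Shared decreases at 2 h were agdC (−1.23, −1.22 and −1.50 in AbfA, BglC and 1542), AN4376 (gdhA), the glutamate dehydrogenase of ammonium assimilation (−1.49, −0.96 and −0.89), the purine gene ade13 (−0.81, −0.93 and −0.75), and metG of sulfur amino acid synthesis (−0.73, −0.79 and −0.71). At 8 h the shared increases were ivoB, ags2, pyrG, sclB (2.11, 1.14 and 2.28) and agdC (1.41, 1.12 and 1.42), and the shared decreases gmdB, tpcA, aah1, btgE (−0.78, −0.67 and −0.67) and hemA, of haem synthesis (−0.66, −0.88 and −0.71). In AbfA at 2 h the calls of tmpA, hsp78, gatA and sxa2 ended without parental replicate 2 (adjusted p = 0.06, 0.05, 0.09 and 0.1), those of hsp78, gatA and sxa2 without parental replicate 3 (0.056, 0.056 and 0.13), and those of tmpA, gatA and sxa2 without AbfA replicate 2 (0.11, 0.15 and 0.21) or 3 (0.12, 0.059 and 0.11). In BglC at 2 h the calls of AN0399, AN0858, tmpA and sxa2 ended without BglC replicate 2 (0.25, 0.063, 0.066 and 0.061), those of AN0399 and AN0858 without parental replicate 2 (0.2 and 0.054), AN0399 without parental replicate 3 (0.1), and AN0399 and sxa2 without BglC replicate 3 (0.064 and 0.058). The count at 2 h was 103 without parental replicate 2, 159 without parental replicate 3, 537, 194 and 192 without BglC replicates 1, 2 and 3, and 166 with only the libraries compared in each fit. The count at 8 h was 382 without parental replicate 1 and 357 without parental replicate 3, and after scaling 567 genes were shared, with 35.1% higher against 116 of 701 before.

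Across genes, which are not independent replicates, the changes from the parental strain at 2 h correlated most between AbfA and 1542 (r = 0.78, covariance 0.348), and less between AbfA and BglC (r = 0.22, covariance 0.076) and between BglC and 1542 (r = 0.23, covariance 0.087). At 8 h r was 0.55 for AbfA and BglC (covariance 0.207), 0.64 for AbfA and 1542 (covariance 0.225) and 0.48 for BglC and 1542 (covariance 0.167). Unchanged groups against the same parental libraries gave r = 0.5 and a covariance of 0.03 at either time. The covariance above that of unchanged groups was 0.318 for AbfA and 1542 at 2 h and 0.046 for AbfA and BglC. Among the 3 recombinant strains 4652 genes differed at 2 h and 2198 at 8 h. With only the libraries compared in the fit the counts were 3009 at 2 h and 2856 at 8 h.

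In the parental strain the nitrate genes crnA, AN0399 (nrtB) and niaD were higher at 8 h than at 2 h, although the list of nitrogen uptake did not pass. The list of the proteasome passed upward, and those of starch use, acetate use and ribosome biogenesis downward. The list calls did not hold with an estimated correlation between genes (adjusted p = 0.29 to 0.70). crnA rose by 5.17 ± 0.89, AN0399 by 4.74 ± 0.51, AN6932 (uapA) by 4.09 ± 0.59, niaD by 3.70 ± 0.56, pmeA, a pectin methylesterase, by 3.62 ± 0.29, and aspf13 by 3.51 ± 0.39. ivoB fell from 743 ± 61 to 3.84 ± 1.49 FPKM (−7.30 ± 0.42), and lower too were mep20 (−5.64 ± 0.55), ags2 (−4.17 ± 0.21), AN3402 (amyB, −3.04 ± 0.46), brlA (−2.97 ± 0.44) and agdC (−2.90 ± 0.20). Of any naming, AN3310 rose by 6.11 ± 0.44 and AN1567 by 5.23 ± 0.78. Of 15 proteasome genes, 14 were higher at 8 h, such as rpn8 (1.07 ± 0.12) and pup1 (0.89 ± 0.14) (camera adjusted p = 0.00011, and adjusted p = 0.70 with an estimated correlation). Of 29 ribosome biogenesis genes, 17 were lower, such as pxr1 (−1.29 ± 0.16) and mrd1 (−1.27 ± 0.16), and 1 was higher, nopA, whose place in this list is doubtful (adjusted p = 4.9e-07, and adjusted p = 0.70 with an estimated correlation). Of 9 genes of starch and maltose use, 6 were lower, 6 also when adjusted over the list alone (adjusted p = 0.0013, and adjusted p = 0.29 with an estimated correlation). Of 7 genes of acetate use, 5 were lower, 5 also when adjusted over the list alone (adjusted p = 0.0058, and adjusted p = 0.65 with an estimated correlation), with acuF at −2.40 ± 0.20. Ribosomal proteins had 5 of 13 lower (adjusted p = 0.027, and adjusted p = 0.89 with an estimated correlation), a call that ended without replicate 3 at 2 h (0.091) or replicate 1 at 8 h (0.13). Of 9201 genes, 4440 changed (2890 higher, 1550 lower), 1343 at least 2-fold, around a median of 0.133. After scaling between libraries 50.5% of the changed genes were higher, against 65.1% before.

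The recombinant strains also changed between 2 h and 8 h. BglC changed in 2974 genes (1996 higher, 978 lower), AbfA in 1755 (1006 higher, 749 lower) and 1542 in 1638 (793 higher, 845 lower). Among genes changed at least 2-fold, 356 were higher and 267 lower in BglC, 197 and 241 in AbfA, and 112 and 276 in 1542. After scaling, 54.1% of the changed genes were higher in BglC against 67.1% before, and 47.0% in AbfA against 57.3% before. In BglC 16 of 29 ribosome biogenesis genes fell, such as dbp3 (−1.05 ± 0.17) (adjusted p = 1.2e-08, and adjusted p = 0.84 with an estimated correlation), and 10 of 15 proteasome genes rose, such as pup1 (0.68 ± 0.14) (adjusted p = 0.0023, and adjusted p = 0.85 with an estimated correlation). In BglC 5 of 15 sterigmatocystin genes fell, 5 also when adjusted over the list alone (adjusted p = 0.0029, and adjusted p = 0.84 with an estimated correlation), and cell wall enzymes had 7 of 22 lower and 3 higher (adjusted p = 0.025, and adjusted p = 0.84 with an estimated correlation). Those last calls ended without BglC 8 h replicate 2 (0.059) and without BglC 2 h replicate 3 (0.061) respectively. In AbfA 3 of 29 ribosome biogenesis genes fell, with pxr1 at −0.85 ± 0.16 (adjusted p = 5.4e-05, and adjusted p = 0.93 with an estimated correlation), a call that ended without AbfA 2 h replicate 1 (0.34). In 1542 8 of 12 siderophore genes fell and 1 rose, with mirB at −2.77 ± 0.67 (adjusted p = 0.0021, and adjusted p = 0.71 with an estimated correlation), and 5 of 17 sterol genes rose, such as erg5 (0.70 ± 0.11) (adjusted p = 0.0047, and adjusted p = 0.71 with an estimated correlation). The list of cell wall enzymes passed upward in 1542 (5 of 22 higher, such as gel1 at 0.79 ± 0.12, adjusted p = 0.035, and adjusted p = 0.71 with an estimated correlation), a call that ended after scaling (0.061) and without replicates 1 (0.054) or 3 (0.051) at 2 h or replicate 1 at 8 h (0.072). In AbfA the count was 994 and 1125 without 8 h replicates 1 and 2, and 868 with only its 6 libraries. In BglC it was 1778 with only its 6 libraries, and in 1542 it was 857 without 2 h replicate 1, and 737 and 818 without 8 h replicates 1 and 2.

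The difference from the parental strain itself changed between 2 h and 8 h for 1538 genes in AbfA, 933 in BglC and 1878 in 1542, tested as the interaction of strain and time. The 3 tests share the 6 parental libraries, so that the strains are not independent of each other here, and no value for unchanged strains was made. Of these genes 98%, 94.2% and 98.2% moved against the parental strain's own change, a direction that the tests favour because they subtract that change. ivoB, mep20 and ags2 moved up relative to the parental strain in each: by 6.62 ± 0.60, 6.56 ± 0.78 and 3.92 ± 0.30 in AbfA, by 5.04 ± 0.60, 4.19 ± 0.78 and 3.28 ± 0.30 in BglC, and by 6.96 ± 0.60, 5.33 ± 0.78 and 4.19 ± 0.30 in 1542. AN0399 (nrtB) moved down by −3.60 ± 0.73, −3.14 ± 0.73 and −4.77 ± 0.73 in the same order, gmdB by −3.33 ± 0.33 in AbfA and −3.04 ± 0.33 in BglC, and crnA by −5.14 ± 1.25 and mirB by −4.32 ± 0.94 in 1542. The list of starch and maltose use passed upward in all 3, through 4 of 9 genes in AbfA and 5 adjusted over the list alone (adjusted p = 0.00088, and adjusted p = 0.21 with an estimated correlation), 6 in BglC and 6 adjusted over the list alone (adjusted p = 6.6e-06, and adjusted p = 0.032 with an estimated correlation), and 5 in 1542 and 6 adjusted over the list alone (adjusted p = 1e-04, and adjusted p = 0.11 with an estimated correlation). The BglC result was the 1 call of all 84 list calls that held with an estimated correlation. List p-values were adjusted within each comparison and not over all 403 tests, so 1 such call may arise by chance. Proteasome genes moved down in AbfA (9 of 15, adjusted p = 0.00025, and adjusted p = 0.81 with an estimated correlation) and in 1542 (12 of 15, adjusted p = 3.4e-05, and adjusted p = 0.53 with an estimated correlation). In 1542 the list of ribosome biogenesis passed upward through a part of its members (9 of 29, adjusted p = 4.8e-07, and adjusted p = 0.53 with an estimated correlation), as did those of sterol synthesis (3 of 17, adjusted p = 0.0032, and adjusted p = 0.53 with an estimated correlation) and folding in the endoplasmic reticulum (3 of 10, 3 adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.37 with an estimated correlation). Siderophores moved down there (8 of 12, adjusted p = 0.0024, and adjusted p = 0.53 with an estimated correlation). In all, 7 lists passed in AbfA, 5 in BglC and 8 in 1542, and each of those not given here for AbfA and BglC lost its call without at least 1 library. Lower changes were 1003 in AbfA, 572 in BglC and 1359 in 1542, so that 34.8%, 38.7% and 27.6% of the calls were higher, against 47.1%, 50.9% and 49.8% after scaling. The median over all genes was −0.147 in 1542. Without parental 2 h replicate 2 the count in 1542 was 1228.

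The genes chosen beforehand for the secretory pathway did not move in 1 direction. bipA, the main chaperone of the endoplasmic reticulum, fell in the parental strain from 656 ± 42.8 FPKM at 2 h to 276 ± 20.5 at 8 h (−1.25 ± 0.16). Against the parental strain it was lower in 1542 at 2 h (−0.85 ± 0.16) and higher in BglC at 8 h (0.51 ± 0.16), and the other 4 changes, between −0.41 and 0.33, did not pass. pdiA, a disulfide isomerase, was lower at 2 h in AbfA (−0.53 ± 0.11) and 1542 (−0.69 ± 0.11). The chaperone gene clxA, for calnexin, was higher at 8 h in BglC (0.50 ± 0.16) and 1542 (0.50 ± 0.16). hacA, the transcription factor of the unfolded protein response, was lower at 2 h in AbfA (−1.39 ± 0.27) and 1542 (−1.51 ± 0.27), and its change in BglC (0.65 ± 0.27) did not pass. The call of bipA in BglC ended without parental replicates 1 (adjusted p = 0.059) or 2 (0.071) or BglC replicates 1 (0.071) or 2 (0.053). That of clxA ended in BglC without parental replicate 1 (0.11) or BglC replicate 1 (0.1), and in 1542 without parental replicates 1 (0.15) or 3 (0.053) or 1542 replicates 2 (0.11) or 3 (0.08).

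The 4 genes of maltose use chosen beforehand fell with time in the parental strain, and against it at 2 h all but 1 of their 12 changes in the recombinant strains passed as lower. The list of 9 starch and maltose genes passed at 2 h in AbfA (camera adjusted p = 0.0029, and adjusted p = 0.45 with an estimated correlation). It did not pass in BglC, with 3 lower (adjusted p = 0.14), or in 1542, with 5 lower and 1 higher (adjusted p = 0.053), and the strains' lists were not compared with each other at 2 h. AN2017 (agdA), an alpha-glucosidase, fell from 151 ± 7.02 to 61.7 ± 1.7 FPKM in the parental strain (−1.28 ± 0.11), AN8953 (agdB), another, from 1680 ± 221 to 391 ± 50.3 (−2.10 ± 0.25), AN2018 (amyA) by 1.23 ± 0.17, and the regulator AN2016 (amyR) by 0.43 ± 0.11. At 2 h AN2016 was lower in AbfA, BglC and 1542 (−0.57, −0.48 and −0.38, SE 0.11), AN2017 likewise (−0.79, −0.72 and −0.47, SE 0.11) and AN2018 too (−1.01, −1.11 and −0.57, SE 0.17). AN8953 was lower in AbfA (−1.17 ± 0.25) and 1542 (−1.08 ± 0.25), while its change in BglC (−0.63 ± 0.25) did not pass. At 8 h AN8953 was higher in 1542 (1.01 ± 0.25), AN2017 in 1542 (0.51 ± 0.11) and BglC (0.35 ± 0.11), and AN2016 was lower in AbfA (−0.44 ± 0.11). The repressor gene creA was lower at 2 h in AbfA (−0.42 ± 0.13) and 1542 (−0.45 ± 0.13), and fell with time in the parental strain (−1.01 ± 0.13). In AbfA the call of creA ended without parental replicates 2 (adjusted p = 0.064) or 3 (0.059) or AbfA replicate 1 (0.069), and with only the 6 libraries compared (0.073). In 1542 it ended without 1542 replicate 3 (0.059), AN2016 without parental replicate 2 (0.078), and AN2018 without 1542 replicate 2 (0.086) or parental replicate 2 (0.072). In BglC, AN2016 at 2 h (0.065) and AN2017 at 8 h (0.069) ended with only the 6 libraries compared, and AN2017 at 8 h also without parental replicates 1 (0.058) or 3 (0.073) or BglC replicates 2 (0.091) or 3 (0.095).

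**Figure D4:**
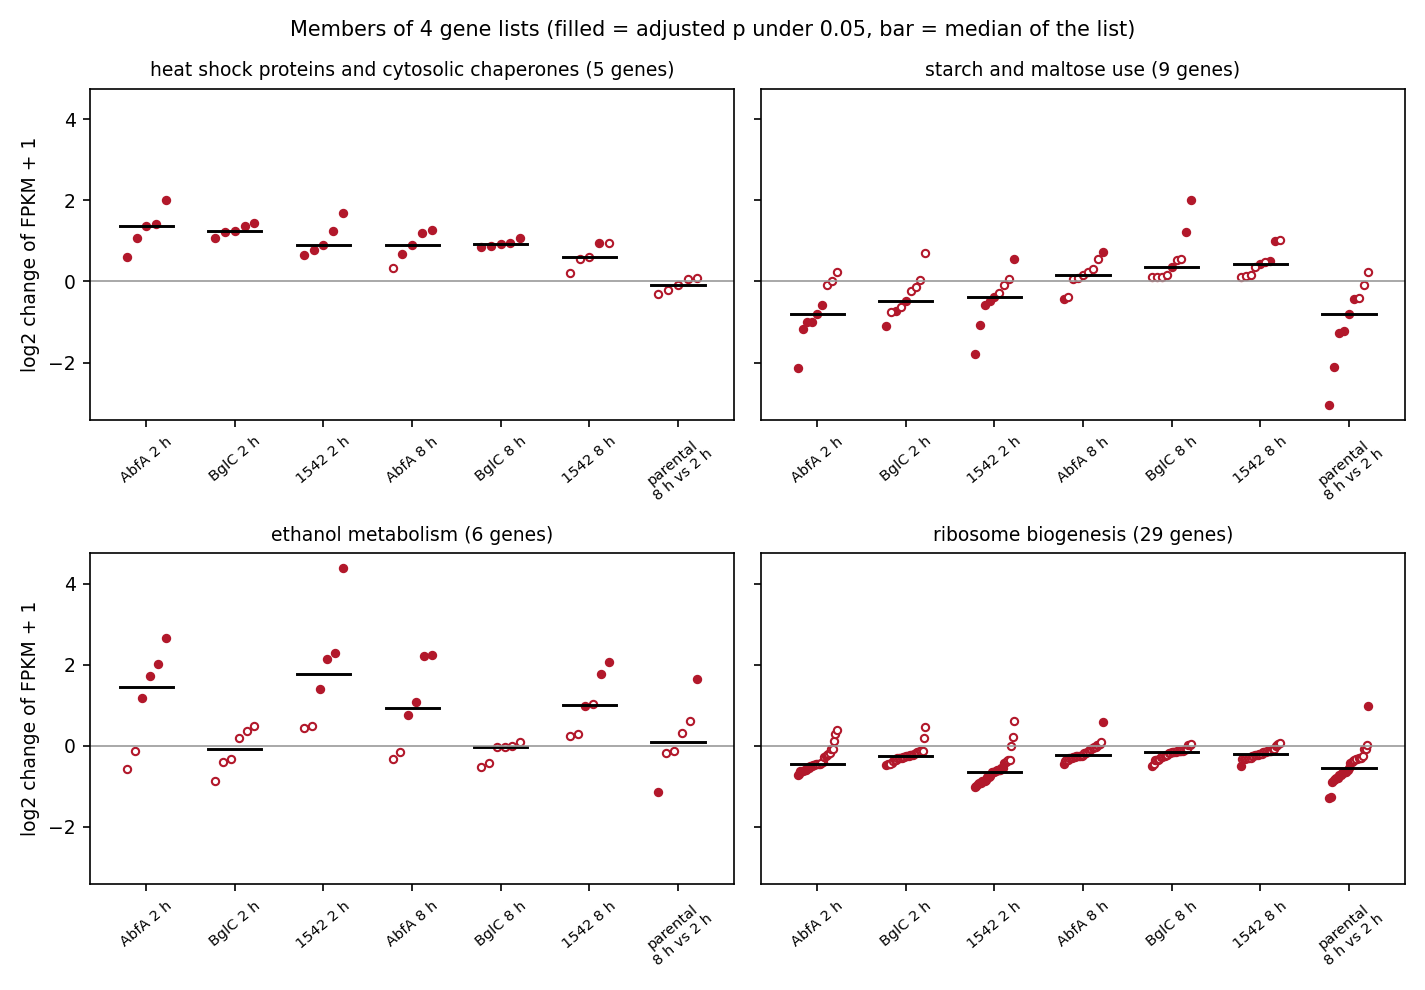
Log2 change of FPKM + 1 of each member of 4 gene lists in the 6 comparisons with the parental strain and between the times in the parental strain, with filled points for genes that passed the limma test and bars for the list's median. The medians of the 5 heat shock genes lie above 0 in the 6 strain comparisons, and those of the 9 starch and maltose genes lie at −0.79 in AbfA at 2 h and 0.42 in 1542 at 8 h.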

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

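The tests of scaling and depth for the count in the parental strain, those of the pyrG paragraph, and those of a single parental library and of folding load for the heat shock genes were chosen after the results they bear on were seen. For scaling and depth the counts under those settings had been seen as well. The splits with strain and time means removed were chosen after the plain splits, and before their own outcome was seen. The other tests were written before. The scaling of the changed differences was first weighed as a pattern of its own, and was replaced by the count in the parental strain once it was clear that centring nearly fixes its outcome. The test of 1 parental library, first written before its outcome as 1 statement over 6 comparisons, met its condition through 1542 at 8 h. It was afterwards divided, in the end by time, since each time has its own parental libraries. The test of folding load was also rewritten after its outcome was seen, and is used to exclude nothing.

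Results stand here because they differ between groups: either the strains differ among each other, or a strain's difference from the parental strain changed between 2 h and 8 h by a test of that change. Among the strains 4652 genes differed at 2 h and 2198 at 8 h. Of 100 splits of the 9 libraries drawn for each, 1 gave as many, the real one, and the highest other gave 4376 and 839, so chance is excluded at that level. Here and below, chance means only the division of these libraries. Each enzyme had 1 strain, so the splits cannot tell an effect of the enzyme from other differences between strains or their cultures. At 2 h the count of another split came close to the real one. Which libraries the split with 4376 genes exchanged was not examined. The changed differences covered 1538 genes in AbfA, 933 in BglC and 1878 in 1542, the last falling to 1228 without parental replicate 2 at 2 h. Plain splits of the 12 libraries gave as many in 9 of 100 for AbfA (highest other 3625), 9 of 100 for BglC (2433) and 2 of 100 for 1542 (2490). By these plain splits chance is excluded for 1542 and not for AbfA and BglC, but relabelling carries the differences between strains and between times into the contrast. With the strain and time means removed first, 1 of 100 splits gave as many in each, the real one, with highest others of 488, 585 and 389, so chance is excluded there.

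In AbfA the difference from the parental strain moved up with time for bipA (0.74), pdiA (0.53), hacA (1.39), AN2017 (0.86), AN8953 (1.41), AN2018 (1.08), creA (0.75), ivoB (6.62), mep20 (6.56), ags2 (3.92) and AN5558 (3.20), all on the log2 scale. It moved down for AN0399 (−3.60), gmdB (−3.33), tpcA (−2.96) and aah1 (−2.36). Without 1 library bipA lost its call for parental replicate 2 at 2 h (limma adjusted p = 0.073) and at 8 h (0.061), AbfA replicates 2 (0.089) and 3 (0.074) at 2 h, and AbfA replicate 3 at 8 h (0.079), and it also lost it with only the libraries compared (0.055). pdiA lost it for parental replicates 2 (0.053) and 3 (0.069) at 2 h, AbfA replicate 2 at 2 h (0.067) and AbfA replicate 3 at 8 h (0.061).

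In BglC it moved up for bipA (0.72), clxA (0.74), AN2016 (0.59), AN2017 (1.07), AN8953 (1.19), AN2018 (1.26), ivoB (5.04), mep20 (4.19), ags2 (3.28) and agdC (2.35), and down for AN0399 (−3.14), gmdB (−3.04), tpcA (−2.83) and aspf13 (−2.32). The call of bipA (limma adjusted p = 0.049) ended without any 1 of the 6 parental libraries (0.058 to 0.11), without BglC replicates 1 (0.098) or 3 (0.094) at 2 h, and without any 1 of the 3 at 8 h (0.062 to 0.1). It ended as well with no filter (0.054), scaling (0.059), no trend (0.053), the replicate block (0.064), voom (0.057) and equal depth (0.054). That of clxA ended without parental replicates 1 to 3 at 2 h (0.053 to 0.095) or 1 at 8 h (0.1), and without BglC replicates 1 and 3 at 2 h (0.079 and 0.073) and at 8 h (0.1 and 0.053), with equal depth (0.051) and with only the libraries compared (0.056). AN2016 lost its call without parental replicate 2 (0.072) or BglC replicate 3 (0.062) at 2 h, or BglC replicate 2 at 8 h (0.06). AN8953 lost it without parental replicates 1 (0.063) or 2 (0.089) at 2 h, parental replicates 1 (0.087) or 2 (0.053) at 8 h, or any 1 of the 3 BglC libraries at 8 h (0.052 to 0.073), and with only the libraries compared (0.1).

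In 1542 it moved up for bipA (0.94), pdiA (0.84), clxA (0.90), AN2016 (0.52), AN2017 (0.98), AN8953 (2.09), AN2018 (0.94), creA (0.66), ivoB (6.96), mep20 (5.33), ags2 (4.19) and agdC (2.92), and down for crnA (−5.14), AN0399 (−4.77), mirB (−4.32) and sidI (−3.99). AN2016 lost its call without 1542 replicates 1 (limma adjusted p = 0.051) or 2 (0.06) at 2 h, 1542 replicates 1 (0.083) or 2 (0.072) at 8 h, or parental replicate 2 at 2 h (0.086) or 8 h (0.053).

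In the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave the most genes in each. The highest other split gave 741 genes against 2939 for AbfA at 2 h, 0 against 2570 at 8 h, 265 against 2135 for BglC at 2 h, 0 against 2576 at 8 h, and 0 against 3517 and 1670 for 1542. Over time it gave 0 against 4440 in the parental strain, 4 against 1755 in AbfA, 162 against 2974 in BglC and 2 against 1638 in 1542. In BglC, where the numbers paired the libraries, the 4 splits that part all 3 pairs had 0 as the highest other, and the 6 other splits reached 162. For genes shared by all 3 strains, 1 of 100 splits gave as many at 2 h (353, highest other 54) and 1 of 100 at 8 h (701, highest other 534), the real ones. These splits mix libraries of different strains, which widens the spread within groups, and each keeps 1 common control group. They therefore cannot tell whether the sharing comes from the common parental libraries, and no conclusion on it is drawn from them.

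More genes changed between 2 h and 8 h in the parental strain (4440) than in any recombinant strain (2974 at most). Scaling between libraries left the parental count at 1.45 times the highest of the others, and equal depth left it at 1.56 times, so neither removed the excess. Both outcomes were known when these tests were written, so they are no independent evidence against either cause. A candidate explanation is that AbfA and 1542 had gone further along the same course by 2 h. Across genes, their difference from the parental strain at 2 h correlated with the change over time in BglC, which shares no library with it (r = 0.36 for AbfA and 0.44 for 1542), while at 8 h r was −0.2 and −0.07. The difference of BglC at 2 h had r = 0.21 with the change over time in 1542, a weaker relation of the same sign, and a peculiarity of the parental cultures was not tested and stays open. At 8 h AbfA, 1542 and BglC all stood short of the parental strain on the first principal component. Their scores were 8 to 16.3, 25.2 to 28.5 and 8.8 to 14.8, against 33 to 42.2. The shortfall was thus not particular to AbfA and 1542, and an earlier start alone does not account for it.

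The pyrG RNA lay above the parental strain in every recombinant strain and time. A rise of the whole pathway is argued against by AN0565, which was lower in 4 of 6 comparisons. Raised transcription around the locus is argued against by its 8 nearest tested genes, whose highest median change was 0.28. A further pyrG copy brought by the transformation may explain the rise. The level differed among strains and no change of the difference with time passed the limma test (lowest adjusted p = 0.63). Other causes tied to the strains could give both, and in simulated data that test found 47% of 2-fold changes. A further copy cannot be told apart from those causes, because the table holds no reads over the mutated site, and the supplements each strain received are not stated.

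The median change of the 9 heat shock genes lay above 0 in all 6 comparisons (1.08 and 0.5 in AbfA, 0.98 and 0.65 in BglC, 0.91 and 0.34 in 1542, at 2 h and 8 h), but in 1542 at 8 h the list did not pass, with 0 of 9 genes called (adjusted p = 0.11). Scaling is argued against as the cause by the lowest median after it, 0.44, although in AbfA at 8 h the list's call ended with it (0.076) while the median went from 0.5 to 0.56. A single parental library is argued against at 2 h, where the lowest median without 1 was 0.82 and no list call ended, although with an estimated correlation between genes none held at either time (adjusted p = 0.35 to 0.90). At 8 h it may account for part of the rise, since without parental replicate 1 the median fell to 0.14 in 1542 and to 0.32 in AbfA, where the list lost its call (adjusted p = 0.14), and to 0.48 in BglC, where the list kept it. The medians of the 10 genes of folding in the endoplasmic reticulum ran from −0.37 to 0.06. At 2 h, where the heat shock medians were highest, those medians were −0.11 in AbfA, −0.19 in BglC and −0.37 in 1542. A rise of the 10 genes as a set was therefore not seen there. They go both ways, and at 8 h bipA and clxA were higher in BglC, in calls that single libraries ended. Folding load can thus not be told apart from other causes, and heat shock from production of the enzymes stays untested.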

How the results depend on the processing

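voom on recovered reads, thinning to 1 depth and the block within BglC were chosen after the data were seen, the other alternatives before. No call of a named gene or list reversed. The total of genes in every comparison stayed within 1.5 times its value under another pseudocount, no filter, scaling, no trend, the replicate block, voom and thinning. The numbers higher and lower did not: scaling moved them from 652 and 1924 to 1055 and 1074 for BglC at 8 h, and raised the higher genes from 499 to 750 for 1542 at 8 h, from 361 to 558 and 519 to 962 for the changed differences in BglC and 1542, and from 116 to 199 shared at 8 h. Stable totals also hid a turnover of the genes called. With scaling 1726 of 2576 calls were kept for BglC at 8 h, 1695 of 2135 for BglC at 2 h, and 1299 of 1670 for 1542 at 8 h. For AbfA at 2 h 2855 of 2939 were kept. Scaling centres the median change near 0 and so nearly fixes a roughly even split. The majority turned with it for 1542 at 2 h, over time in AbfA (892 higher, 1006 lower) and 1542, and for the changed difference in BglC. It also turned without AbfA replicate 1 at 2 h over time in AbfA (884, 1053), without 1542 replicate 3 at 8 h over time in 1542, and for genes shared at 2 h with voom and without BglC replicates 1 or 2. With only the libraries compared in the fit, counts moved both ways. They were 1319 for AbfA at 2 h, 637 for BglC at 2 h, 3009 among the strains at 2 h, 868 and 1778 over time in AbfA and BglC, and 166 shared at 2 h, all lower by over 1.5 times, while they rose to 2878 for AbfA at 8 h, 2856 among the strains at 8 h, 1772 over time in 1542 and 856 shared at 8 h, and rose for the changed difference in 1542 too. List calls fell from 84 to 1 with an estimated correlation. Leaving out each library in turn gave 1747 to 3520 and 1363 to 2648 genes for AbfA at 2 h and 8 h, 976 to 3064 and 1558 to 2530 for BglC, and 2411 to 3520 and 957 to 1783 for 1542. It gave 3731 to 4982 and 1561 to 2021 among the strains, and 3760 to 4159, 994 to 1937, 2306 to 2988 and 737 to 1596 over time in the parental strain, AbfA, BglC and 1542. The changed differences gave 1091 to 2157, 646 to 1164 and 1228 to 2017, the shared genes 103 to 537 and 357 to 880, and the list calls 69 to 93. Fewer libraries alone lower such counts, and the cause of the rest was not tested. Of 844 calls of named genes, 509 held under every alternative. The others ended in 1186 of 6300 fits without 1 library, in 184 with only the libraries compared, in 75 with scaling, 71 with thinning, 38 without the filter, 29 with voom, 18 without the trend and 14 with the other pseudocount. Named results that had not passed did so in 11 fits without 1 library, 9 with scaling and 2 with only the libraries compared. Of 84 list calls, 78 of 624 fits without 1 library ended one, scaling ended 9 and voom 2. Libraries of the same number correlated no better than others (mean r −0.006 against 0.004, the best match having the library's own number in 6 of 24), and 1 of 10 comparisons had every pair above 0.1. Under the replicate block 37 named-gene calls and 2 list calls ended, and the counts were within 1.5 times. Depth limits low values, where 1 read stands for up to 0.1401 FPKM in a gene of 1 kb.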

Other observations

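The test of neighbouring genes was chosen after the result was seen, and the runs of genes and AN5430 were chosen after their values were seen. Some of the genes with large changes lay in runs of adjacent genes, most did not, and BglC at 2 h had no run of at least 3. The longest was on chromosome II, where AN7893 to AN7899 (8 tested genes) were lower in BglC at 8 h with a median log2 change of −3.4, while in 1542 at 2 h AN7893 to AN7895 (3 genes) and AN7897 to AN7903 (8 genes) were higher with medians of 5.7 and 4.47, and at 8 h AN7897 to AN7899 (4 genes) were higher in 1542 (3.04). In AbfA at 2 h AN7893 to AN7895 were higher as well (2.92). On chromosome VII AN8981 to AN8978 (4 genes), which include AN8979 (alcA), were higher in 1542 at 2 h (4.09). On chromosome VIII the 3 genes AN1008 to AN1006 were higher in 1542 at 2 h (3.04), the 3 genes AN0531 to AN0528 in 1542 at 2 h and 8 h (3.41 and 3.54), and the 3 genes AN10023 to AN10038 in AbfA at 2 h (2.46) and BglC at 8 h (2.92). In AbfA at 8 h AN9246 to AN9249 (4 genes, 2.37), AN9252 to AN11205 (4 genes, 2.75) and AN0501 to AN0499 (3 genes, 2.72) were higher there. In 1542 AN8539 to AN8544 (3 genes, chromosome V) were higher at 2 h (3.45), and AN3333 to AN3330 (3 genes, chromosome VI) lower at 8 h (−2.61).

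A hypothesis was that such runs are more frequent than the number of changed genes alone gives. Adjacent pairs with changes of at least 2 (log2) in the same direction outnumbered the highest of 1000 shuffles of the gene order in 5 of 6 comparisons. The pairs against the highest shuffle were 15 against 8 for AbfA at 2 h, 19 against 6 at 8 h, 3 against 3 for BglC at 2 h, 17 against 5 at 8 h, and 35 against 8 and 15 against 5 for 1542. This is consistent with clusters of genes regulated together, and neighbours that share reads were not tested. Over windows of 41 neighbouring genes the medians of the strains' changes ran from −0.33 to 0.5 in AbfA, from −0.4 to 0.4 in BglC and from −0.29 to 0.41 in 1542.

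A few genes differed widely in level between groups. AN0284 was at 61.7 ± 9.3 FPKM at 2 h and 121 ± 11.5 at 8 h in BglC (SD, n = 3), against group means between 0.486 and 0.754 in the other strains. AN2573 was at 39.4 ± 10.3 FPKM in the parental strain at 8 h and at 0.919 ± 0.481 or less in the other groups, and AN5459 likewise at 9.21 ± 1.69 there. AN5430 was at 97.4 ± 74.2 and 406 ± 250 FPKM in BglC, with 25.4 ± 21.6 and 40.2 ± 28.2 in AbfA and 6.45 ± 6.27 at most in the parental strain. AN8308 was at 1110 ± 525 and 3390 ± 701 FPKM in 1542, and in the parental strain its 8 h libraries spread widely (344 ± 489).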
